A study of Mus musculus with 17 samples.

How the data were processed

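RNA from laser-microdissected lung tissue of SPC/c-Raf transgenic mice and non-transgenic mice was measured on 17 Affymetrix mouse exon arrays: 4 dysplasias, 4 adenocarcinomas, 4 pieces of unaltered transgenic lung and 5 non-transgenic lungs. Per the labels, the authors stained cryosections with haematoxylin, reduced ribosomal RNA and amplified the RNA before hybridisation. The deposited values are log2 RMA values of core transcript clusters, which the authors computed in Expression Console; GCOS was named for the scans, with its version not given. They ran from 1.13 to 14.3, with no missing value, and were used without a filter. The study looked at alternative splicing; exon values were not analysed here. No genome build was stated, so no coordinates are given.

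Of 23238 transcript clusters, 14939 carried 1 gene symbol, 989 several and 7310 none. Those without a symbol include 6577 numbered below 6000000. Their median SD over the arrays was 0.452, against 0.217 for transcript clusters with 1 symbol. Counts of calls are therefore counts of transcript clusters, not of genes. For gene lists, a gene with several transcript clusters was taken at the one with the highest mean. Groups, sexes, ages and animals were taken from the labels. They name 13 animals or pairs of animals. Of these labels, 4 belong to both a dysplasia and an unaltered array, and 3 arrays carry the names of 2 animals. Pairing came from the labels: the correlation of deviations from the group means was 0.21, 0.08, 0.15 and -0.01 for the 4 pairs, against -0.23 to 0.15 for other combinations, so the values by themselves do not show the pairs.

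All 6 comparisons came from 1 fit in limma 3.58.1 (R 4.3.3) with 4 group means, labelled sex as a covariate and the animal as a random block (duplicateCorrelation, correlation 0.247), followed by eBayes and Benjamini-Hochberg adjustment over all transcript clusters, with a threshold of 0.05. On 4 arrays the Y-linked genes Eif2s3y and Kdm5d went against the labelled sex, so this covariate is uncertain. Fold changes are adjusted for it and can differ from the difference between printed group means. In all, 38 gene lists of 943 genes, 767 of them measured, were fixed before the data were examined, as were the comparisons, the tests and most alternative settings. Lists were tested with cameraPR on the moderated statistics with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. Lists not mentioned for a comparison were not called there.

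The rule for named genes was also fixed before the data were examined: a set of genes of the model, the 10 largest rises and 10 largest falls among called transcript clusters whose groups of arrays do not overlap, and up to 4 members of each called list. For dysplasia against unaltered tissue the same direction in all 4 pairs was asked instead. Transcript clusters with no or several symbols, unnamed gene models, receptor and immunoglobulin segments and small RNA genes were left out of the ranking. The text prints part of what the rule names: the first 4 rises, the first 4 falls and the first 2 members of the 6 lists with the smallest p and of the ERK list, in order of size. The model genes are printed in full for dysplasia against unaltered tissue and adenocarcinoma against non-transgenic lung. How far down each order to print was decided after the values were seen, and an earlier choice of examples was dropped because it had favoured genes whose calls held in the alternatives. Losses of calls were therefore counted over all genes of the rule, printed or not. Alas2, a member of the red blood cell list under the rule, was added to the print after its values were seen. Additional named lists and genes in the shared changes and figure panels come from the same rule.

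Alternatives were no block, a fixed replicate block, no sex term, animals labelled male only, age as a covariate, fits of only the 2 groups compared, filters on low values, 1-symbol transcript clusters, quantile normalization and cyclic loess between arrays, eBayes with trend and robust, array weights, leaving out arrays whose labels name 2 animals, and leaving out each array. For lists, the mean of a gene's transcript clusters was also tried. Chosen after seeing the data were sex taken from the Y-linked genes, leaving out non-transgenic replicates 4 and 5 or 1 to 3, and leaving out the unnamed transcript clusters numbered below 6000000. Other splits of the arrays were counted, up to 100 per comparison.

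The steps were tested on simulated data with 17 arrays and the same design. A log2 change of 1 was recovered in 70.1% to 83.6% of the changed transcript clusters and a change of 0.5 in 23.9% to 55.2%. There were 3 to 9 false calls among 23008 unchanged ones. The noise was drawn independently for each transcript cluster, and few were changed. It held no sex effect and no distance of non-transgenic replicates 4 and 5 from 1 to 3. These rates may therefore not hold for the real arrays. The number of arrays limits the precision. The size of a difference from a group mean below the lower quartile of its arrays is not well determined; besides Cldn2 and Gkn2 this holds for Pln (4.68) and Tnnc1 (4.82) in dysplasia, Tk1 (4.43) and Lif (4.72) in unaltered tissue and Fibin (4.96) in adenocarcinoma.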

Results

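Gene expression was measured in lung tissue of SPC/c-Raf mice, a transgenic line in which the promoter of the surfactant protein C gene drives the transgene in alveolar epithelium and lung tumours form, and in healthy non-transgenic lung. Cells were cut out of stained cryosections with a laser and catapulted into a cap, and their RNA was hybridised to Affymetrix mouse exon arrays. The 17 arrays came from 4 dysplasias, 4 adenocarcinomas, 4 pieces of transgenic lung without a visible lesion (unaltered tissue) and 5 non-transgenic lungs. Dysplasia and unaltered tissue shared the same 4 animal labels, all male and 5 to 6 months old. The adenocarcinoma animals were 11.5 to 14 months old and the non-transgenic animals 7 to 11 months. The adenocarcinoma animals were therefore the oldest, and those of dysplasia and unaltered tissue were younger than the non-transgenic ones. Ages overlapped only between dysplasia and unaltered tissue. In the other comparisons an age covariate cannot fully part age from group, so a call lost with it does not show an effect of age. The study was built around alternative splicing; exon values were not analysed here, and everything below refers to 23238 transcript clusters, of which 14939 carry exactly 1 gene symbol. The median log2 value of an array lay between 6.67 and 6.85. The number of arrays limits the precision.

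The first principal component held 34.3% of the variance and ran from the non-transgenic arrays, at scores of -42.1 to -27.6, through unaltered tissue and dysplasia to the adenocarcinomas, at 49.1 to 56. Dysplasia replicate 3, at 29.9, was the dysplasia nearest to the tumours. Non-transgenic replicates 4 and 5 stood apart from replicates 1 to 3, with Spearman correlations of 0.975 to 0.98 between the 2 sets against at least 0.989 within them. The Y-linked genes Eif2s3y and Kdm5d were low on those same 2 arrays and high on the other 15. On 4 arrays, non-transgenic replicates 2, 3 and 5 and adenocarcinoma replicate 2, their level went against the labelled sex. The growth factor gene Areg was not analysed here, and the lung factor Nkx2-1 appeared only in a transcript cluster that names several genes.

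**Figure D1:**
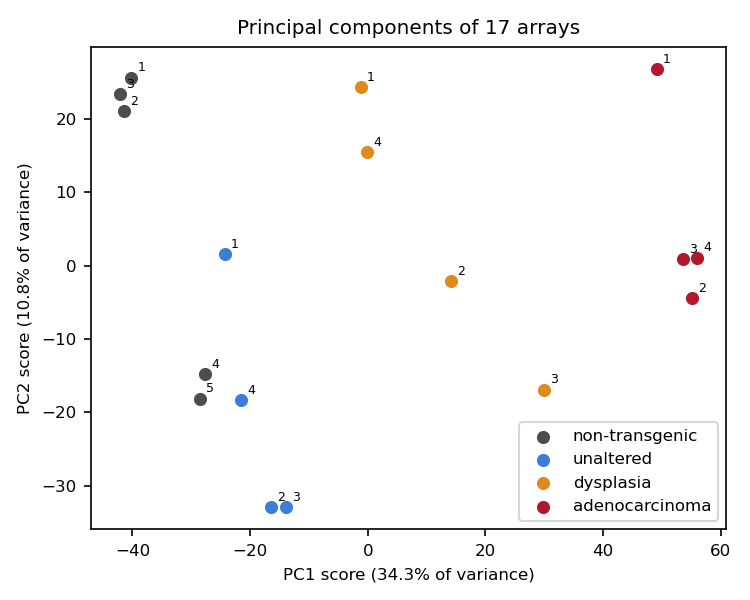
Scores of the 17 arrays on the first 2 principal components of the log2 values, with 1 point per array, coloured by group and numbered by replicate. The 4 adenocarcinomas lie at 49.1 to 56 on the first component, above all other arrays, and non-transgenic replicates 4 and 5 lie away from replicates 1 to 3 on the second.

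Dysplasia was first set against unaltered lung of the same 4 animals, which asks what separates an early lesion from the tissue around it. The set test called mitosis and epithelial junction genes higher in the lesions and endothelial and fibroblast genes lower, and lost all 4 calls at adjusted p = 0.0508 to 0.0635 with an estimated correlation. Atp13a4, a P-type ATPase gene, rose by 2.66 ± 0.13 on the log2 scale (SE, 4 arrays against 4), the tight junction gene Cldn4 by 2.55 ± 0.21 and the sialyltransferase gene St8sia6 by 2.51 ± 0.21. Ereg, which encodes the EGF receptor ligand epiregulin (transcript cluster 6932387), rose from a log2 level of 7.27 ± 0.81 to 9.87 ± 0.93 (SD, n = 4 each), a log2 fold change of 2.60 ± 0.33 (SE). The largest falls were those of S100a9, a neutrophil gene, at -1.44 ± 0.28, the heart muscle genes Pln and Tnnc1, at -1.31 ± 0.31 and -1.25 ± 0.32, and Cdo1, a cysteine oxidation gene, at -1.12 ± 0.18. None of these 4 falls passed with the animal as a fixed replicate block, where adjusted p was 0.0783, 0.169, 0.133 and 0.0502.

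Among the genes fixed for the model, the type II cell gene Sftpb rose by 0.34 ± 0.06 in dysplasia, the type I cell gene Hopx fell by 0.61 ± 0.09, and the endothelial adhesion gene Pecam1 fell by 0.74 ± 0.10 (SE, 4 arrays against 4). The feedback genes Dusp6 and Spry2 rose by 0.96 ± 0.11 and 0.92 ± 0.10, the cyclin gene Ccnd1 by 0.75 ± 0.12 and the topoisomerase gene Top2a by 1.03 ± 0.13. The transcription factor genes Etv4 and Etv5 rose by 0.72 ± 0.18 and 0.38 ± 0.09, and the receptor gene Egfr fell by 0.46 ± 0.08, but with a fixed replicate block none of the 3 passed, at adjusted p of 0.0663, 0.0712 and 0.0708. Mki67, a proliferation marker, was called at 0.70 ± 0.23 (adjusted p = 0.0417) and lost without dysplasia replicate 1, 2 or 3 (adjusted p = 0.0774, 0.122 and 0.0967), without unaltered replicate 1, 2 or 4 (0.0946, 0.137 and 0.1), and with the fixed block (0.0566). Sftpc, close to the top of the scale at 14.21 ± 0.03 (SD, n = 4), Ager, Scgb1a1, Spry4 and Cdkn2a did not pass, at 0.02 ± 0.04, 0.05 ± 0.05, 0.37 ± 0.44, 0.09 ± 0.09 and -0.13 ± 0.10. Cyclic loess scaling turned Sftpc, Ager and Spry4 to -0.07, -0.05 and -0.02.

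Of 36 measured endothelial cell genes 31 fell in dysplasia, none rose and 5 did not pass (33 fell adjusted over the list alone); the median log2 fold change was -0.61, with the receptor genes Ramp2 and Ednrb at -0.95 ± 0.09 and -0.91 ± 0.15 (SE, 4 arrays against 4). Of 37 mitosis genes 33 rose and none fell (36 rose adjusted over the list alone), with a median of 0.70, Nek2 at 1.32 ± 0.22 and Prc1 at 1.27 ± 0.15. Of 27 epithelial junction genes 21 rose and none fell (22 and 1 adjusted over the list alone), with a median of 0.74 and Cldn3 at 1.29 ± 0.16 after Cldn4. Of 23 alveolar type II cell genes 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.38, the protease gene Ctsh at 1.18 ± 0.11 and Sftpd at 0.78 ± 0.08. Adjusted p with an estimated correlation was 0.0635, 0.0508, 0.0635 and 0.12 for these 4 lists, so the calls of the set test were lost there.

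Of 32 DNA replication genes 19 rose in dysplasia and none fell (23 adjusted over the list alone), with a median of 0.35, the methylation maintenance gene Uhrf1 at 0.95 ± 0.13 and Tk1 at 0.88 ± 0.18 (SE, 4 arrays against 4); Tk1 did not pass with a fixed replicate block (adjusted p = 0.0754). Of 26 fibroblast genes 15 fell and 1 rose, in both adjustments, with a median of -0.38, the proteoglycan gene Ogn at -1.04 ± 0.19, not passed with the fixed block (adjusted p = 0.0699), and the integrin gene Itga8 at -1.02 ± 0.15. Of 22 ERK pathway output genes, which MEK signalling switches on, 11 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.39 and Dusp4 at 0.96 ± 0.09. These 3 calls were lost at adjusted p = 0.18, 0.0508 and 0.118 with an estimated correlation. The set test also called EGF family genes (median 0.62) higher and called type I cell (-0.29), smooth muscle (-0.26), cardiac muscle (-0.77), mesothelial (-0.67), interferon response (-0.17) and red blood cell genes (-0.23) lower. It called gastrointestinal and progression genes higher at a median of 0.00 and a mean of 0.41. Of these 8, red blood cell genes, of which 2 of 7 fell, with Alas2 at -0.93 ± 0.08, kept the call at adjusted p = 0.0125 with an estimated correlation, and the others lost it at adjusted p = 0.12 to 0.458 with an estimated correlation. The mean of the cardiac genes was 6.15 and 6.92 in unaltered replicates 2 and 3 and 5.84 in replicate 4, against 5.23 to 5.57 in all other arrays.

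In total 4558 transcript clusters passed limma's test between dysplasia and unaltered tissue, 3357 higher and 1201 lower, and 285 higher and 25 lower changed at least 2-fold. With the animal as a fixed replicate block the count was 1881, and without the arrays whose labels name 2 animals it was 2127. The share of higher calls depended on scaling: quantile normalization gave 2128 higher and 2239 lower, and cyclic loess gave 2200 and 1976.

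**Figure D2:**
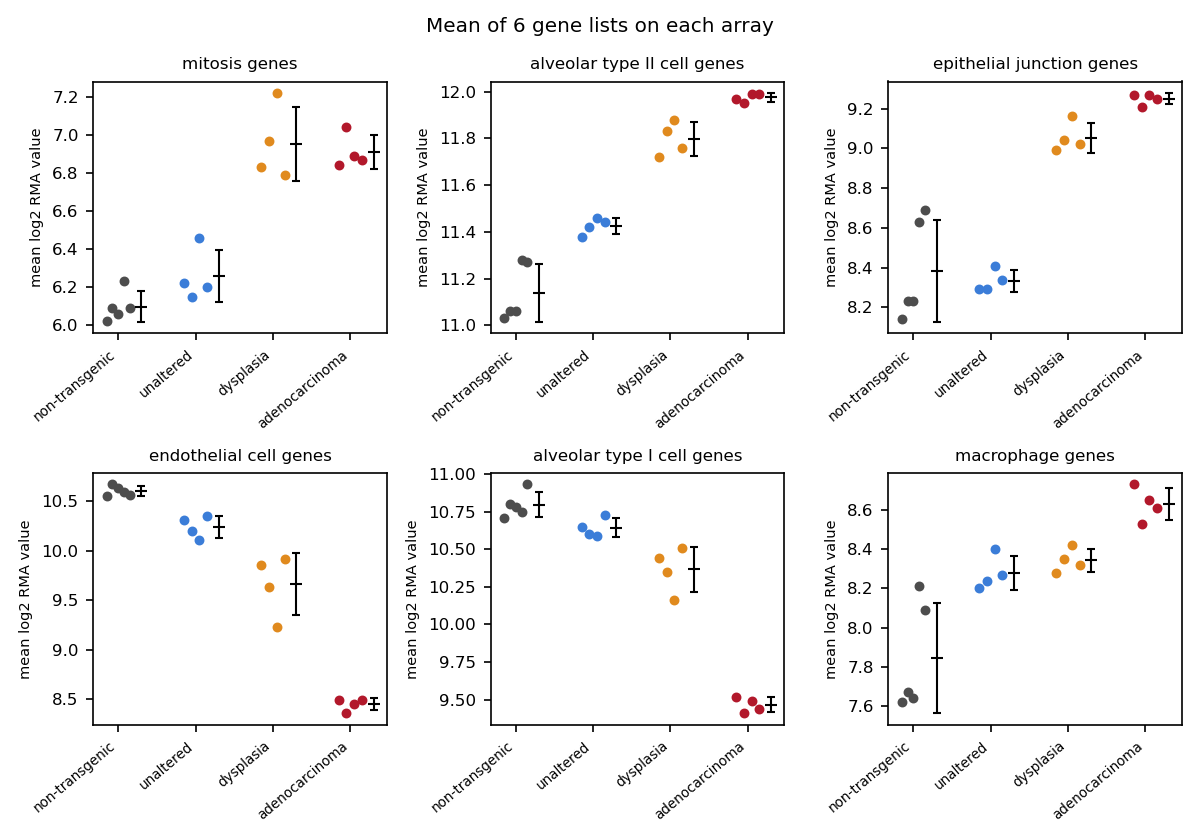
Mean log2 value of 6 gene lists on each of the 17 arrays, with 1 point per array and, beside each group, its mean with bars of 1 SD. Mitosis, type II and junction genes are higher in both lesion groups than in non-transgenic lung, and endothelial genes are lowest in adenocarcinoma.

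Unaltered transgenic tissue was compared with non-transgenic lung to ask what carrying the transgene does where no lesion is seen. The fibrinogen gene Fgg rose by 2.57 ± 0.29 on the log2 scale (SE, 4 arrays against 5), Ereg by 1.99 ± 0.43, the secreted glycoprotein gene Lrg1 by 1.74 ± 0.08 and St8sia6 by 1.64 ± 0.27. Dbp, a transcription factor gene driven by the circadian clock, fell by 1.99 ± 0.45, the paraoxonase gene Pon1 by 1.77 ± 0.43, the chemokine gene Ccl5 by 1.76 ± 0.30 and the palmitoyltransferase gene Zdhhc17 by 1.45 ± 0.24. Lrg1 went from 8.38 ± 0.12 (SD, n = 5) to 10.03 ± 0.08 (SD, n = 4). Without non-transgenic replicate 5 the calls of Ereg, Dbp and Pon1 were lost (adjusted p = 0.0694, 0.108 and 0.145), and that of Pon1 also without unaltered replicate 2 or 4 (0.0537 and 0.0508).

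Of 23 alveolar type II cell genes 12 rose and 1 fell in unaltered tissue (14 and 1 adjusted over the list alone), with a median of 0.29; the list was still called at adjusted p = 0.0382 with an estimated correlation. Its largest changes were Il33 at 0.80 ± 0.20 and Slc6a14 at -0.73 ± 0.19 (SE, 4 arrays against 5). Of 23 macrophage genes 8 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.39, Gpnmb at 1.23 ± 0.11 and the mannose receptor gene Mrc1 at 1.06 ± 0.18; without non-transgenic replicates 1 to 3 the median was -0.03, although the list was still called. Of 37 mitosis genes 2 rose, Anln at 0.71 ± 0.12 and Kif23 at 0.60 ± 0.14, and none fell (4 and 1 adjusted over the list alone). Of 14 neutrophil genes 2 rose, the histamine synthesis gene Hdc at 1.43 ± 0.15 and the iron-binding lipocalin gene Lcn2 at 0.69 ± 0.15 (4 rose adjusted over the list alone). Of 24 gastrointestinal and progression genes 3 rose and none fell (4 rose adjusted over the list alone), with the mucin gene Muc4 at 0.78 ± 0.21 and Cd44 at 0.65 ± 0.13. Of 36 endothelial genes 6 fell and none rose (14 fell adjusted over the list alone), with Plvap at -0.94 ± 0.14 and Tmem100 at -0.54 ± 0.15. The last 5 lists lost the call at adjusted p = 0.307, 0.549, 0.357, 0.0779 and 0.852 with an estimated correlation, and the endothelial list also without non-transgenic replicates 1 to 3 (adjusted p = 0.316).

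The set test also called cardiac muscle genes (median 0.47) higher and T and NK cell (-0.37) and interferon response genes (-0.37) lower in unaltered tissue, and fatty acid and lipid synthesis genes higher at a median of -0.03 and a mean of 0.05. All 4 were lost at adjusted p = 0.348 to 0.566 with an estimated correlation, and the lipid list also without non-transgenic replicate 1 (adjusted p = 0.132) or replicates 1 to 3 (0.301). The mean of the cardiac list was 6.04 ± 0.7 in unaltered tissue (SD, n = 4) and 5.5 ± 0.05 in non-transgenic lung (SD, n = 5). Unaltered replicate 1 did not share the rise. Of 22 ERK pathway output genes 1 rose, none fell and 21 did not pass, none adjusted over the list alone, and the list was not called (median -0.15, mean -0.06, set test direction up; adjusted p = 0.954).

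In total 1912 transcript clusters, of which 1553 carried 1 gene symbol, passed limma's test, 312 higher and 1600 lower. This count was not stable. It was 1 when only these 2 groups were fitted, 16 with age as a covariate, 551 in animals labelled male, of which non-transgenic replicate 5 was low in Y-linked genes, 3317 without the sex term, and 3643 with sex taken from the Y-linked genes. It was 382 without non-transgenic replicate 5, 835 without unaltered replicate 2 and 1266 without unaltered replicate 4. Without non-transgenic replicates 4 and 5 it was 997, and without replicates 1 to 3 it was 3641. The direction turned with scaling: quantile normalization, which moved the median of all transcript clusters by 0.107, gave 533 higher and 347 lower, and cyclic loess gave 525 and 415. Array weights gave 1155, and leaving out the arrays whose labels name 2 animals gave 244. Of the 20 genes named here, 19 lost the call in at least 1 alternative, and Lrg1 in none. Without non-transgenic replicate 5, Il33, Slc6a14, Kif23, Cd44 and Tmem100 were lost (adjusted p = 0.0508, 0.168, 0.121, 0.0744 and 0.137). Without non-transgenic replicate 1, Il33, Lcn2 and Muc4 were lost (0.0887, 0.056 and 0.141), and without replicate 2 or 3, Tmem100 (0.0551 and 0.0564). Leaving out unaltered replicates 1 to 4 in turn, Il33, Slc6a14, Muc4 and Tmem100 were each lost at least once, at adjusted p of 0.0509 to 0.0975.

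Dysplasia was compared with non-transgenic lung as the early lesion against healthy tissue. Ereg rose from 5.20 ± 0.26 (SD, n = 5) to 9.87 ± 0.93 (SD, n = 4), a log2 fold change of 4.60 ± 0.43 (SE). St8sia6 rose by 4.15 ± 0.27, the fetuin gene Fetub by 3.74 ± 0.40 and the receptor phosphatase gene Ptprn by 3.32 ± 0.21. Ccl5 fell by 1.87 ± 0.30, the secreted factor gene Fibin by 1.82 ± 0.26, the membrane glycoprotein gene Gpm6a by 1.79 ± 0.25 and the mesenchymal transcription factor gene Tcf21 by 1.71 ± 0.21.

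Of 37 mitosis genes 34 rose in dysplasia against non-transgenic lung and none fell (36 rose adjusted over the list alone), with a median of 0.92, Kif23 at 1.85 ± 0.14 and Prc1 at 1.77 ± 0.20 (SE, 4 arrays against 5). Of 36 endothelial genes 34 fell and none rose (35 fell adjusted over the list alone), with a median of -0.97, Plvap at -1.61 ± 0.14 and the prostaglandin dehydrogenase gene Hpgd at -1.38 ± 0.19. Of 23 type II cell genes 19 rose and none fell (19 and 1 adjusted over the list alone), with a median of 0.68, Ctsh at 1.66 ± 0.14 and Muc1 at 1.19 ± 0.12. Of 24 gastrointestinal and progression genes 9 rose and none fell, in both adjustments, with a median of 0.15, Cldn2 at 3.21 ± 0.25 and the stomach gene Gkn2 at 2.83 ± 0.34. Their non-transgenic levels, 3.91 and 4.36, lay below the lower quartile of those arrays (5.02 to 5.11) and near those of Y-linked genes where these were low, so the size of both differences is not well determined. These 4 lists were also called with an estimated correlation, at adjusted p = 0.00439, 0.0243, 0.000718 and 0.00439.

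Of 27 junction genes 18 rose and 1 fell in dysplasia against non-transgenic lung (19 and 1 adjusted over the list alone), with Cldn4 at 2.49 ± 0.28 and the protease gene St14 at 1.32 ± 0.16 (SE, 4 arrays against 5). Of 26 interferon response genes 14 fell and 1 rose (19 and 2 adjusted over the list alone), with Gbp3 and Gbp2 at -1.28 ± 0.17 and -1.17 ± 0.16. Of 22 ERK pathway output genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), with Etv4 at 1.21 ± 0.24, lost when only these 2 groups were fitted (adjusted p = 0.0741), and Myc at 1.11 ± 0.23, lost without non-transgenic replicates 1 to 3 (adjusted p = 0.0791). The 3 calls were lost at adjusted p = 0.157, 0.164 and 0.171 with an estimated correlation. The set test also called macrophage (median 0.44), DNA replication (0.27), EGF family (0.35) and fatty acid and lipid synthesis genes (0.13) higher. It called type I cell (-0.43), fibroblast (-0.38), smooth muscle (-0.36), mesothelial (-0.94), T and NK cell (-0.25), B and plasma cell (-0.47) and red blood cell genes (-0.21) lower. Of these 11, red blood cell genes, of which 3 of 7 fell, with Alas2 at -1.40 ± 0.11, kept the call at adjusted p = 0.0125 with an estimated correlation, and the others lost it at adjusted p = 0.164 to 0.488 with an estimated correlation. Without non-transgenic replicates 1 to 3 the red blood cell list was lost (adjusted p = 0.0593). The B and plasma cell list was also lost without dysplasia replicate 3 (adjusted p = 0.0653) or non-transgenic replicate 1 (0.159), and without replicates 1 to 3 (0.397).

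In total 3034 transcript clusters passed limma's test, 1292 higher and 1742 lower, and 290 and 288 changed at least 2-fold. The count was 1127 with age as a covariate, of which 59.4% were higher against 42.6% without it, 1155 with only these 2 groups, 2008 without the arrays whose labels name 2 animals, and 5269 with sex taken from the Y-linked genes.

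Adenocarcinoma was compared with non-transgenic lung as the tumour against healthy tissue. Ereg rose by 4.98 ± 0.39 (SE, 4 arrays against 5), Fetub by 4.85 ± 0.36, St8sia6 by 4.59 ± 0.24 and Cldn2 by 4.58 ± 0.22, of uncertain size because of its low non-transgenic level of 3.91. Ogn fell from 11.33 ± 0.15 (SD, n = 5) to 6.17 ± 0.32 (SD, n = 4), a log2 fold change of -5.22 ± 0.23. Fibin fell by 4.43 ± 0.24, the incretin receptor gene Glp1r by 3.98 ± 0.28 and Cdo1 by 3.98 ± 0.21.

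Among the genes fixed for the model, Etv4 rose by 1.95 ± 0.21 in adenocarcinoma, Ccnd1 by 1.15 ± 0.14, Dusp6 by 1.10 ± 0.13, Spry2 by 0.87 ± 0.11 and Etv5 by 0.78 ± 0.10 (SE, 4 arrays against 5). Mki67 and Top2a rose by 1.11 each, with SE of 0.26 and 0.15, Sftpb rose by 1.03 ± 0.07 and the tumour suppressor gene Cdkn2a by 0.70 ± 0.12. Egfr fell by 1.81 ± 0.09, Hopx by 1.82 ± 0.10 and Pecam1 by 1.99 ± 0.11. The club cell gene Scgb1a1 was called at -1.59 ± 0.51 and lost without adenocarcinoma replicate 2 (-0.43, adjusted p = 0.614), without non-transgenic replicate 2 or 5 (adjusted p = 0.0513 and 0.0595), and with sex taken from the Y-linked genes (-0.78, adjusted p = 0.352). Sftpc, Spry4 and Ager did not pass, at 0.05 ± 0.05, -0.12 ± 0.10 and -0.10 ± 0.06. Sftpc turned to -0.02 and -0.16 with quantile and cyclic loess scaling and passed as lower with the latter (adjusted p = 0.0322), and Ager passed at -0.23 with both. Sftpc lay close to the top of the scale, at 14.18 in non-transgenic lung and 14.23 in adenocarcinoma, so its values say little about a change.

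**Figure D3:**
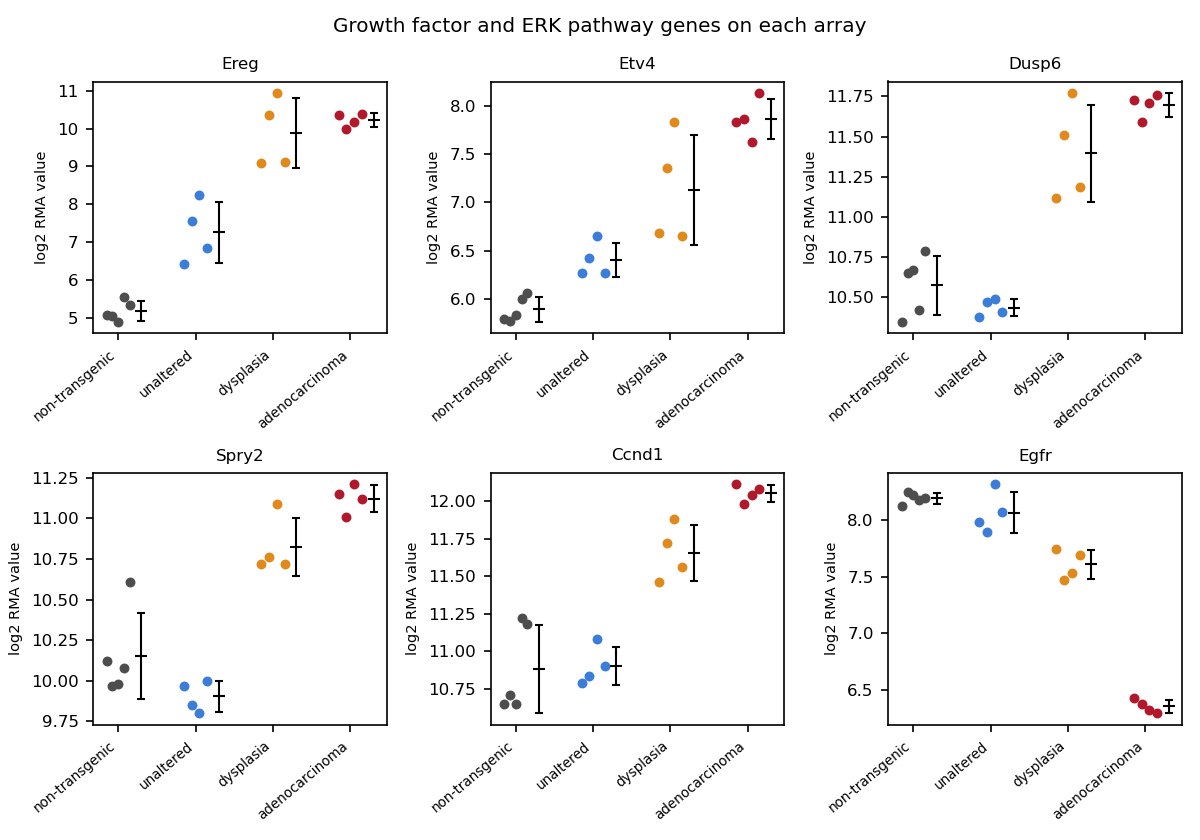
Log2 values of 6 growth factor and ERK pathway genes on each of the 17 arrays, with 1 point per array and, beside each group, its mean with bars of 1 SD. Ereg is lowest in non-transgenic lung (mean 5.20) and highest in adenocarcinoma (mean 10.22), and Egfr runs the other way, from 8.18 to 6.36.

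Of 36 endothelial cell genes 34 fell in adenocarcinoma against non-transgenic lung and none rose, in both adjustments, with a median of -2.17, Tmem100 at -3.97 ± 0.13 and Hpgd at -3.95 ± 0.18 (SE, 4 arrays against 5). Of 21 type I cell genes 17 fell and 2 rose, in both adjustments, with a median of -1.30, Igfbp2 at -3.20 ± 0.17 and Spock2 at -2.68 ± 0.14. Of 26 fibroblast genes 17 fell and 5 rose (18 and 6 adjusted over the list alone), with a median of -1.27 and Itga8 at -3.90 ± 0.17 after Ogn. Of 23 type II cell genes 20 rose and 1 fell (20 and 2 adjusted over the list alone), with a median of 0.78, Ctsh at 2.09 ± 0.12 and Muc1 at 1.62 ± 0.11. These 4 lists were also called with an estimated correlation, at adjusted p = 0.00154, 0.00352, 0.00154 and 0.00515. Of 37 mitosis genes 34 rose and none fell (36 rose adjusted over the list alone), with a median of 0.83, Kif23 at 2.11 ± 0.13 and Prc1 at 1.64 ± 0.18. Of 27 junction genes 19 rose and 3 fell (19 and 4 adjusted over the list alone), with a median of 0.84, Cldn4 at 2.91 ± 0.25 and Cldn3 at 2.02 ± 0.18. Of 22 ERK pathway output genes 13 rose and 2 fell, in both adjustments, with a median of 0.66 and Myc at 1.38 ± 0.21 after Etv4. The last 3 calls were lost at adjusted p = 0.146, 0.191 and 0.191 with an estimated correlation.

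The set test also called macrophage (median 0.99), DNA replication (0.35), fatty acid and lipid synthesis (0.30) and gastrointestinal and progression genes (0.39) higher in adenocarcinoma than in non-transgenic lung. It called smooth muscle (-1.15), mesothelial (-1.22), T and NK cell (-0.48), B and plasma cell (-0.80), red blood cell (-0.10), interferon response (-0.49), mesenchymal transition (-0.56), basement membrane (-0.26) and xenobiotic genes (-0.72) lower. Of these 13, the gastrointestinal and red blood cell lists kept the call at adjusted p = 0.00697 and 0.00241 with an estimated correlation, and the others lost it at adjusted p = 0.0626 to 0.485 with an estimated correlation. Without non-transgenic replicate 1 the lipid and basement membrane lists were lost (adjusted p = 0.0576 and 0.0632), and without adenocarcinoma replicate 2 the basement membrane list (0.0616). Both were also lost with age as a covariate (adjusted p = 0.0595 each), and without non-transgenic replicates 1 to 3 the lipid, basement membrane and B and plasma cell lists were lost (0.0604, 0.127 and 0.124). Of the 7 measured red blood cell genes 3 fell and none rose, with a mean of -0.71 that came mainly from Alas2, a haem synthesis gene, at -3.72 ± 0.10 (SE, 4 arrays against 5). The EGF family list was not called (adjusted p = 0.0671), although 8 of its 13 genes rose and 2 fell, in both adjustments.

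In total 6365 transcript clusters passed limma's test between adenocarcinoma and non-transgenic lung, 2809 higher and 3556 lower, and 592 and 1107 changed at least 2-fold. The majority turned with quantile normalization, which gave 3593 higher and 3055 lower. With age as a covariate the count was 4125.

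Adenocarcinoma was compared with dysplasia as the later against the earlier lesion. The cornified envelope gene Sprr1a rose by 2.20 ± 0.22 (SE, 4 arrays against 4), the collagen gene Col15a1 by 2.17 ± 0.15, the metallothionein gene Mt2 by 2.17 ± 0.45 and the neutrophil antigen gene Cd177 by 2.05 ± 0.20. Ogn fell by 3.70 ± 0.23, the airway secretoglobin gene Scgb3a2 by 3.44 ± 0.77, Pon1 by 2.97 ± 0.39 and Spata18 by 2.93 ± 0.76. Scgb3a2 and Spata18 had their highest group means in dysplasia, at 9.24 ± 0.09 and 9.58 ± 0.03 (SD, n = 4). They lay at 7.68 ± 1.42 and 7.84 ± 1.66 in non-transgenic lung (SD, n = 5). In unaltered tissue they lay at 8.23 ± 1.55 and 7.79 ± 1.09 (SD, n = 4). With age as a covariate Mt2, Cd177, Scgb3a2, Pon1 and Spata18 did not pass (adjusted p = 0.777, 0.0865, 0.41, 0.103 and 0.466), at log2 fold changes of 1.31, 2.01, -4.51, -3.65 and -4.06, so only that of Mt2 was clearly smaller. Spata18 was also lost without dysplasia replicate 1 or 4 (adjusted p = 0.0598 and 0.0553) and without adenocarcinoma replicate 3 or 4 (0.0666 and 0.062).

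Of 36 endothelial cell genes 30 fell between dysplasia and adenocarcinoma and none rose (33 fell adjusted over the list alone), with a median of -1.18, Tmem100 at -2.72 ± 0.14 and Ednrb at -2.61 ± 0.18 (SE, 4 arrays against 4). Of 21 type I cell genes 15 fell and none rose (15 and 1 adjusted over the list alone), with a median of -0.98, Igfbp2 at -1.91 ± 0.18 and Sema3a at -1.76 ± 0.11. Of 26 fibroblast genes 16 fell and 1 rose (16 and 3 adjusted over the list alone), with a median of -0.84 and Itga8 at -2.66 ± 0.17 after Ogn. Of 23 xenobiotic and NRF2 target genes 10 fell and 3 rose (13 and 4 adjusted over the list alone), with a median of -0.74, the cytochrome P450 gene Cyp4b1 at -2.65 ± 0.13 and Fmo1 at -2.63 ± 0.19. With an estimated correlation these 4 lists were still called, at adjusted p = 0.000379, 0.000222, 7.16e-06 and 0.0327.

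Of 14 ciliated cell genes 6 fell between dysplasia and adenocarcinoma and none rose (11 fell adjusted over the list alone), with a median of -1.43, Tppp3 at -1.73 ± 0.16 and Hydin at -1.62 ± 0.48 (SE, 4 arrays against 4). The mean of this list was 7.21 in dysplasia, 6.54 in non-transgenic lung, 6.46 in unaltered tissue and 5.86 in adenocarcinoma. That of the club cell list was 9.87, 9.45, 9.31 and 8.61 in the same order. Neither list was called for dysplasia against non-transgenic or unaltered tissue. Whether airway cells were captured with the dysplasias was not tested. Hydin was lost without dysplasia replicate 1, 2 or 4 (adjusted p = 0.108, 0.0803 and 0.101) and without any 1 adenocarcinoma (0.0672 to 0.109). Of 18 cholesterol synthesis genes 8 fell and none rose (10 fell adjusted over the list alone), with a median of -0.35, Sqle at -0.77 ± 0.13 and Sc5d at -0.60 ± 0.09. Of 22 ERK pathway output genes 4 rose and 1 fell (8 and 2 adjusted over the list alone), with Etv4 at 0.74 ± 0.22 and the early response gene Ier3 at -0.42 ± 0.13. Etv4 was lost without dysplasia replicate 1 or 4 (adjusted p = 0.13 and 0.124) and without any 1 adenocarcinoma (0.051 to 0.138). Ier3 was lost without any 1 dysplasia (0.0705 to 0.134) and without adenocarcinoma replicate 2 or 4 (0.109 and 0.166). The 3 lists lost the call at adjusted p = 0.336, 0.327 and 0.41 with an estimated correlation. The set test also called type II cell (median 0.23), macrophage (0.31), glycolysis and hypoxia (0.14), gastrointestinal and progression (0.19) and junction genes (0.28) higher. It called club cell (-0.84), smooth muscle (-0.66), mesothelial (-0.28), T and NK cell (-0.23), mesenchymal transition (-0.20) and basement membrane genes (-0.15) lower, and red blood cell genes lower at a median of 0.00 and a mean of -0.34. Of these 12, red blood cell genes kept the call at adjusted p = 0.0106 with an estimated correlation, and the others lost it at adjusted p = 0.0862 to 0.69 with an estimated correlation. The glycolysis list was lost without dysplasia replicate 2 or 3 (adjusted p = 0.0715 and 0.137) and without adenocarcinoma replicate 1 or 3 (0.0748 and 0.0611), and with age as a covariate its median was -0.01 (adjusted p = 0.406). The ERK output, junction, mesenchymal transition and basement membrane lists were also lost with age as a covariate (adjusted p = 0.199, 0.283, 0.0675 and 0.245). Of the 7 red blood cell genes only Alas2 passed, at -2.32 ± 0.10 (SE, 4 arrays against 4). Of 37 mitosis genes none passed limma's test, in either adjustment, and the list was not called (median -0.10; adjusted p = 0.637).

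In total 2425 transcript clusters passed limma's test between the lesions, 880 higher and 1545 lower. At least 2-fold changes were 60 higher and 429 lower, of which 41 and 377 carried 1 gene symbol. Quantile normalization gave 1226 calls higher and 1410 lower. The count was 152 with age as a covariate, of which 3.3% were higher against 36.3% without it, 1285 without the arrays whose labels name 2 animals, 4965 with array weights and 3721 with sex taken from the Y-linked genes. With age as a covariate Igfbp2, Sqle, Sc5d, Hydin, Etv4 and Ier3 did not pass either (adjusted p = 0.0521, 0.101, 0.138, 0.541, 0.796 and 0.768), at -2.01, -1.13, -0.79, -2.29, 0.62 and -0.40.

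Adenocarcinoma was compared with unaltered transgenic tissue, which carries the transgene but no visible lesion. Mt2 rose by 4.05 ± 0.45 (SE, 4 arrays against 4), the synaptic organiser gene Cbln1 by 4.01 ± 0.34, Ankrd22 by 3.85 ± 0.20 and Cldn2 by 3.82 ± 0.23, of uncertain size because its unaltered level of 4.74 lay below the lower quartile of the unaltered arrays (4.97 to 5.04). Ogn fell by 4.74 ± 0.23, Itga8 by 3.68 ± 0.17 and Cdo1 by 3.53 ± 0.22, and the retinol acyltransferase gene Lrat fell by 3.57 ± 0.26. With age as a covariate Mt2 did not pass (3.18, adjusted p = 0.117).

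Of 36 endothelial genes 34 fell in adenocarcinoma against unaltered tissue and none rose, in both adjustments, with a median of -1.81, Ednrb at -3.52 ± 0.18 and Tmem100 at -3.43 ± 0.14 (SE, 4 arrays against 4). Of 21 type I cell genes 16 fell and 2 rose (17 and 3 adjusted over the list alone), with a median of -1.48, Igfbp2 at -2.54 ± 0.18 and Sema3e at -2.30 ± 0.16. Of 26 fibroblast genes 17 fell and 3 rose (19 and 5 adjusted over the list alone), with a median of -1.04. These 3 lists were also called with an estimated correlation, at adjusted p = 0.000673, 0.00178 and 4.54e-05. Of 27 junction genes 20 rose and 1 fell, in both adjustments, with a median of 0.88, Cldn4 at 2.97 ± 0.25 and Cldn3 at 2.03 ± 0.18. Of 23 type II cell genes 18 rose and 2 fell, in both adjustments, with a median of 0.57, Ctsh at 1.61 ± 0.13 and Lgi3 at 1.28 ± 0.15. Of 37 mitosis genes 28 rose and none fell (31 rose adjusted over the list alone), with a median of 0.62, Kif23 at 1.51 ± 0.13 and Prc1 at 1.14 ± 0.18. Of 22 ERK pathway output genes 13 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.60, Etv4 at 1.46 ± 0.22 and the cytokine gene Lif at 1.38 ± 0.25. The last 4 calls were lost at adjusted p = 0.164, 0.136, 0.337 and 0.136 with an estimated correlation.

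The set test also called DNA replication (median 0.43), oxidative phosphorylation (0.33) and gastrointestinal and progression genes (0.13) higher in adenocarcinoma than in unaltered tissue. It called smooth muscle (-0.81), mesothelial (-0.95), T and NK cell (-0.14), red blood cell (-0.24), interferon response (-0.34), cholesterol synthesis (-0.32), mesenchymal transition (-0.38), basement membrane (-0.29) and xenobiotic genes (-0.30) lower. Of these 12, the smooth muscle and red blood cell lists kept the call at adjusted p = 0.0401 and 0.000673 with an estimated correlation, and the others lost it at adjusted p = 0.136 to 0.599 with an estimated correlation. Without adenocarcinoma replicate 1, 2 or 4 the oxidative phosphorylation list was lost (adjusted p = 0.0531, 0.0608 and 0.0502), as it was without unaltered replicate 1 or 2 (0.071 and 0.0662), and without adenocarcinoma replicate 1 the T and NK cell list (0.0633). The T and NK cell, interferon response, oxidative phosphorylation and basement membrane lists were lost with age as a covariate (adjusted p = 0.0592, 0.0889, 0.0975 and 0.057). Of the 7 red blood cell genes 3 fell, and Alas2 fell most, by 3.25 ± 0.10 (SE, 4 arrays against 4). Of 57 splicing factor genes 15 rose, 3 fell and 39 did not pass, in both adjustments, and the list was not called (median 0.14; adjusted p = 0.142).

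In total 5996 transcript clusters passed limma's test, 3751 higher and 2245 lower. At least 2-fold changes were 610 higher and 713 lower, of which 458 and 634 carried 1 gene symbol. Cyclic loess gave 2922 calls higher and 3009 lower. With age as a covariate the count was 1160, of which 32.6% were higher against 62.6% without it, and Etv4, Lgi3, Prc1 and Lif did not pass (adjusted p = 0.206, 0.14, 0.245 and 0.376), at 1.35, 1.03, 1.08 and 1.20.

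The changes of the lesions against non-transgenic lung were set side by side. Of the transcript clusters called in both, 1169 were higher in both, 1606 lower in both and 7 moved in opposite directions, where independent lists would share 156.2 and 266.6; that expectation leaves out the control arrays common to both, so it is not the value without a change. Across transcript clusters, which are not independent replicates, the log2 fold changes correlated at 0.771. Unchanged groups simulated as independent noise in the same design, with 5 control arrays in common, gave 0.543. The simulated noise leaves out structure of the real controls, such as the distance of replicates 4 and 5 from 1 to 3. The covariance was 0.186 against 0.032 simulated, a difference of 0.153. When the controls were split so that the lesions had no control array in common, the mean correlation over 20 splits was 0.623 (0.437 to 0.691). The test of the difference between these changes is the comparison of adenocarcinoma with dysplasia, with its 2425 calls; Ogn and Itga8 fell further in the tumours.

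**Figure D4:**
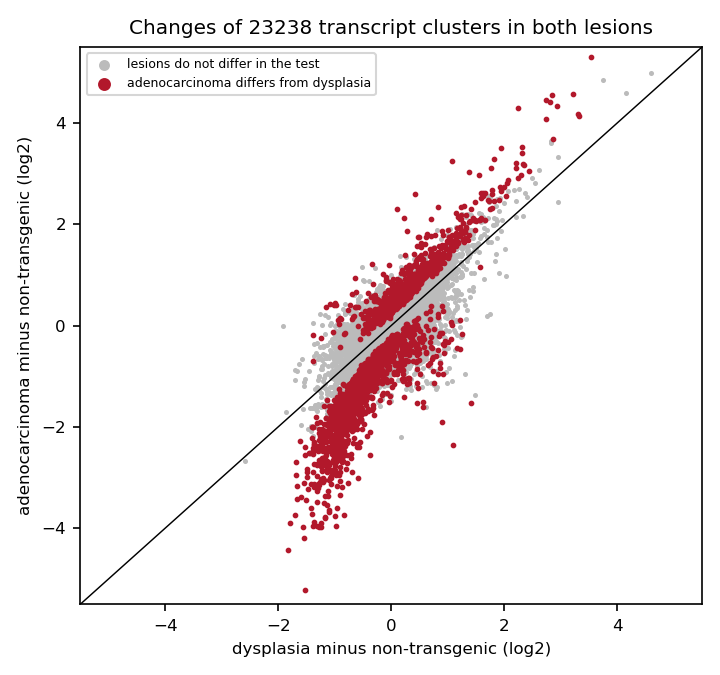
Log2 fold change of each of 23238 transcript clusters against non-transgenic lung, in dysplasia (horizontal axis) and in adenocarcinoma (vertical axis), with the line of equal change. The 2425 transcript clusters that differ between the lesions are in red, and more of them are lower in adenocarcinoma (1545) than higher (880).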

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

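The tests on non-transgenic replicates 4 and 5, on clock genes and on endothelial genes were chosen only after the results were seen; the counts of other splits and the search for arrays far from their group were planned.

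In 7 groups of arrays, 1 array lay far from the others of its group. Among adenocarcinomas these were replicate 2 for fibroblast genes (mean 8.35, others 8.4 to 8.41), replicate 1 for MHC class II genes (10.56, others 10.68 to 10.7), replicate 3 for RAF and RAS pathway components (9.21, others 9.17 to 9.18) and replicate 2 for Scgb1a1 (9.69, others 12.59 to 13.05). The others were Top2a in non-transgenic replicate 4 (7.24, others 6.86 to 6.89), and Spry2 in non-transgenic replicate 5 (10.61, others 9.97 to 10.12) and in dysplasia replicate 3 (11.09, others 10.72 to 10.76). These were 3 of 152 groups for lists, where chance gives 7.6, and 4 of 68 for genes, where chance gives 3.4. The changes of dysplasia and adenocarcinoma against non-transgenic lung differed from each other in 2425 transcript clusters by limma's test of that difference.

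Non-transgenic replicates 4 and 5 stood apart from replicates 1 to 3. Club and ciliated cell genes were higher there by a median of 1.25 over 28 genes, at percentile 100 of matched random lists, so airway cells may have been captured with them; other lists were as extreme there, with macrophage, oxidative phosphorylation and xenobiotic genes at percentile 100, junction and mesothelial genes at 99.98, MHC class II genes at 99.95, glycolysis and hypoxia genes at 99.89, endothelial genes at 0.32, and B and plasma cell and splicing factor genes at 0. Airway cells cannot account for the Y-linked genes Eif2s3y and Kdm5d, which were both lower, with a difference of -3.49 for the one nearer to 0. That difference was known before the test and does not tell what separates the arrays in other transcript clusters. In 3 non-transgenic arrays the Y-linked level went against the labelled sex, so labels that name another animal stay open. Sex of the animals cannot be told apart from the rest, since 0 arrays of other groups had a low Y-linked level.

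Clock genes differed between arrays. Over 13 animals, deviations of 7 clock output genes and of 4 genes of the opposite arm from their group means had Pearson's r of -0.86 (permutation p = 0.00015, adjusted 3e-04) and Spearman's rho of -0.81 (permutation p = 0.00137), with 2 relations tested. Without non-transgenic replicate 5 and adenocarcinoma replicate 2, the farthest, r was -0.81 (permutation p = 0.0029), and a candidate explanation is the time of day of collection, which the labels do not give. The transgene alone cannot be told apart from it: unaltered and non-transgenic means of the output arm differed by -0.77, and the non-transgenic arrays ranged over 1.07, but over 0.25 without replicate 5. The comparison with 0.25 replaced that with 1.07 after both were seen; the first had argued against the transgene alone.

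Endothelial genes were lower in lesions. A loss of all non-epithelial cell types alike is argued against only by macrophage genes. Their median in adenocarcinoma against non-transgenic lung lay 3.16 above the endothelial one (bootstrap 95% interval 2.65 to 3.52). Both medians were known when this test was chosen, and its prediction was reworded after the value was seen. No other non-epithelial cell list was called higher there, and fibroblast, smooth muscle, mesothelial and lymphocyte lists were called lower. The set test's macrophage call was lost at adjusted p = 0.29 with an estimated correlation. The bootstrap drew genes, so its interval leaves out the spread between animals. The macrophage mean went from 7.85 ± 0.28 (SD, n = 5) to 8.63 ± 0.08 (SD, n = 4). The endothelial mean went from 10.6 ± 0.05 to 8.45 ± 0.06 on the same arrays. The endothelial medians were -2.13 and -2.19 after quantile normalization and cyclic loess. These moved the median of all transcript clusters by only 0.049 and 0.003 in this comparison. They could hardly have brought the endothelial median near 0, so they cannot decide on a shift from the normalization. Fewer endothelial cells in the captured lesions may explain it. The count of 34 of 36 genes lower and 0 higher is the pattern itself and does not test this. Lower expression per cell was not tested. The adenocarcinoma animals were the oldest, but the median was -0.61 between dysplasia and unaltered tissue with the same animal labels. The endothelial median was -2.24 in adenocarcinoma against non-transgenic lung with age as a covariate. The ages of those groups did not overlap, so the covariate cannot fully part age from tumour.

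Other splits of the arrays were counted, and in each comparison only 1 split, the real one, gave as many calls. The real split was the only 1 of 100 counted with as many calls for unaltered tissue against non-transgenic lung (1912, highest other 1360). The same held for dysplasia against it (3034 and 1886) and adenocarcinoma against it (6365 and 5051). The highest others there put 4 of the 5 non-transgenic arrays against the rest. It was the only 1 of 35 for adenocarcinoma against dysplasia (2425, highest other 2) and against unaltered tissue (5996 and 1). These shares lie under 0.05, so a random division of the arrays seldom gives as many calls. They cannot show what the labels stand for, since the age of the animals also differed between the groups of these comparisons. For dysplasia against unaltered tissue the 8 splits that part every pair are too few for a share under 0.05 (4558, highest other 2).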

How the results depend on the processing

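Sex from the Y-linked genes, the removal of sets of non-transgenic arrays and leaving out the unnamed transcript clusters numbered below 6000000 were chosen only after the results were seen; the other alternatives were planned.

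With age as a covariate the number of called transcript clusters was 16 for unaltered against non-transgenic tissue, 1127 for dysplasia and 4125 for adenocarcinoma against non-transgenic lung, 152 for adenocarcinoma against dysplasia and 1160 against unaltered tissue. Unaltered against non-transgenic tissue gave 3317 without the sex term, 551 in animals labelled male (non-transgenic replicate 5 among them, low in Y-linked genes), 1 with only these groups, 880 after quantile normalization, 940 with cyclic loess, 1155 with array weights, 997 without non-transgenic replicates 4 and 5 and 3641 without replicates 1 to 3. Dysplasia against non-transgenic lung gave 1155 with only these groups, and adenocarcinoma against dysplasia gave 4965 with array weights. Without the arrays naming 2 animals, counts were 2127 for dysplasia against unaltered tissue, 244 for unaltered against non-transgenic tissue, 2008 for dysplasia against non-transgenic lung and 1285 for adenocarcinoma against dysplasia. A fixed replicate block gave 1881 for dysplasia against unaltered tissue. Sex from the Y-linked genes gave 3643, 5269 and 3721 for unaltered tissue and dysplasia against non-transgenic lung and for adenocarcinoma against dysplasia. Leaving out each array in turn gave 382 to 2573 for unaltered against non-transgenic tissue. Alternatives that leave out arrays test fewer samples. The ages of the groups overlapped only between dysplasia and unaltered tissue, so the age covariate runs closely with the group in the other comparisons. Calls lost with it therefore cannot be put down to age. For the remaining alternatives the cause was not tested. The other 122 counts stayed within 1.5 times.

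The correlation of lesion changes, 0.771, was 0.88 above the median level, 0.808 without non-transgenic replicates 4 and 5 and with sex from the Y-linked genes, 0.79 without replicates 1 to 3, 0.623 with split controls, and 0.769 to 0.793 with each non-transgenic array left out.

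Genes that had not passed turned sign: in dysplasia against unaltered tissue, Ager to 0.00 and -0.05 and Spry4 to -0.01 and -0.02 with quantile and loess scaling, Sftpc to -0.07 with loess, and Spry4 to 0.00 without dysplasia replicate 3 (0.00 to 0.15 over left-out arrays). In adenocarcinoma against non-transgenic lung Sftpc, close to the top of the scale, turned to -0.02 and -0.16, and passed as lower at -0.16 with loess (adjusted p = 0.0322). The cause was not tested.

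Over all genes of the naming rule, the 160 printed pairs of a gene and a comparison lost the call in 196 of 3937 recomputed values, gained it with the sign kept in 2 and turned sign in 8, of which 1, Sftpc with loess, also passed; the 393 pairs not printed lost it in 551 of 9574, gained it with the sign kept in 41 and turned sign in 69. At least 1 alternative ended the call or turned the sign for 52 of the 160 and 182 of the 393. Of 101 list calls, 78 were lost with an estimated correlation; the other alternatives ended a call in 73 of the values, and none turned the direction of the set test. Medians of 4 lists did change sign in some alternatives, such as glycolysis genes in adenocarcinoma against dysplasia (-0.01 with age as a covariate) and macrophage genes in unaltered against non-transgenic tissue (-0.03 without non-transgenic replicates 1 to 3). Changes near the noise of the arrays were recovered less often in simulation.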
